A study of Homo sapiens with 24 samples.

How the data were processed

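Gene expression was measured with Affymetrix Human Genome U133 Plus 2.0 arrays, per the series' design text, on 24 tissue samples in 4 groups of 6. Total RNA was amplified to cDNA and biotin-labelled before hybridization, per the labels' protocols. Each sample's group and replicate number came from its title.

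The authors deposited 1 table of 54675 probe sets by 24 arrays. Its values are a linear ratio: the deposited value of 51279 probe sets (93.8%) had a median of 1 over the 24 arrays, within 0.001, so each of these probe sets had been divided by its own median. The other 3396 probe sets had medians below 1 and a wider spread (median SD of the log2 values 1.63, against 0.67 for the rest), and what they were divided by is not given in the sources used here. MAS5 is named in the submitters' processing notes without a version, and how arrays were scaled to one another is not given in the sources used here. Because every probe set is relative to itself, the values of different probe sets cannot be compared and brightness over background is unknown. The median value of a column, over all probe sets, ran from 0.734 to 1.142, and the scaling between arrays was kept as deposited. No pair of arrays held identical values. The number of arrays, 6 per group, limits the precision.

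Probe sets were named through the platform annotation provided with the table, which can be old. Of all probe sets, 41097 had 1 gene symbol, 1801 had several and 11777 had none; only those with 1 symbol were used. The symbols of 41043 of these were matched by gene ID to a RefSeq gene table of assembly GRCh38.p14, used for names and chromosomes only. The 62 control probe sets, 84 probe sets of sex-linked genes, and probe sets with a median other than 1 were left out of the gene tests. A gene with several probe sets was represented by 1 of them, chosen from the annotation alone: by probe set type, then a curated mRNA accession, then the older part of the array. This left 18918 genes. For some named genes the values of other probe sets are given, mostly where these went the other way.

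Log2 of the ratio was taken without an offset. Genes were tested with limma 3.58.1 in R 4.3.3: lmFit with 4 group means over the 24 arrays, leaving 20 residual degrees of freedom, and eBayes, with 2-sided moderated tests of 6 contrasts and Benjamini-Hochberg adjustment over the genes tested. A gene was called at an adjusted p under 0.05. Fold changes are ratios of geometric means, and errors of log2 fold changes are standard errors (SE) of the fit. The 38 gene lists (710 different genes, of which 641 were tested) were tested with limma's camera, 2-sided, with a preset correlation of 0.01 and adjustment over the lists, for lists with at least 4 genes tested. Camera asks whether a list moves against the other genes measured. It was repeated with an estimated correlation, and limma's fry, which asks whether a list's genes move one way on balance, was run beside it. The score of a list on an array is the mean log2 value of its genes, and scores were compared between groups with 2-sided exact permutation tests, adjusted over the 38 lists; the smallest p such a test can give for 6 against 6 arrays is 0.00216. The ratio of 3' to 5' probe sets of GAPDH and ACTB on each array, a sign of RNA integrity and amplification, was compared between groups in the same way, adjusted over 12 tests.

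The groups, the gene and list tests, the gene lists, most alternatives and the rule for named genes were chosen before the data were examined. The tests of list scores, the 3'/5' ratio as a covariate and a few other alternatives were added later. The plan assumed intensities. For ratios, its offset, its filter on dim probe sets, its choice of the brightest probe set and its trend of the spread with brightness have no meaning, so they were replaced as described, the trend after a first fit had been seen; the planned settings were run as an alternative. The rule for named genes took, for each comparison, the 6 largest rises and 6 largest falls among called genes (where none was called, the 3 smallest p in each direction), up to 3 called members of at most 6 lists at an adjusted p under 0.05, and a fixed panel of 12 genes. Of that panel 1 gene is not analysed here. Immunoglobulin and T cell receptor segments, HLA genes and a few genes that commonly vary between people in copy number were never named. A few other genes, named as such, were picked from list members or from small counts after their values were seen.

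The alternatives were another filter, offset, scaling between arrays, probe set, spread model, array weights, the groups in the fit, the replicate number as a block, a gland marker score or the 3'/5' ratio as a covariate, another list test, and leaving out 1 array at a time. The gland marker score of an array is the mean z-score of the tested submucosal gland genes over the arrays, and differs from the score of that list. The gene test and camera with the preset correlation were run on simulated data for nasal polyp against control UT with 18918 genes. The other tests were not simulated. The simulated genes varied independently of one another, so the shares that follow need not hold for genes that move together. Among genes simulated with a 4-fold change 53% were called, with a 2-fold change 37.3%, and with a 1.49-fold change 4.5%; among the genes with the smaller spread 100% and 72.7% of the 4-fold and 2-fold changes were called. Of 68 calls 5 were of unchanged genes, and with no change simulated 0 genes were called by limma. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and figures.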

Results

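Gene expression was compared in sinonasal tissue from patients with chronic rhinosinusitis (CRS), a lasting inflammation of the nose and sinuses, and from control subjects. Uncinate tissue (UT), the mucosa of a thin bony fold in the lateral nasal wall, made up 18 samples: 6 from control subjects, 6 from patients with CRS without nasal polyps (CRSsNP) and 6 from patients with CRS with nasal polyps (CRSwNP). The fourth group held 6 samples of nasal polyp tissue, inflamed outgrowths of the mucosa, from patients with CRSwNP. The comparisons ask how diseased tissue differs from control tissue, and how polyps differ from uncinate tissue. Values are linear ratios of a probe set to its own median over the 24 arrays, analysed as log2. The labels give separate samples but do not say that each came from a different donor, so the p-values measure the spread between these samples.

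The median value of an array ran from 0.969 to 1.105 in nasal polyps, from 0.884 to 1.082 in control UT, from 0.906 to 1.142 in CRSsNP UT and from 0.734 to 1.046 in CRSwNP UT. The 3'/5' ratio of ACTB, which rises when RNA is degraded or amplified only in part, was lower in nasal polyps than in control UT by a log2 difference of -1.15 and than in CRSwNP UT by -1.26, in 2-sided exact permutation tests (adjusted p = 0.0259 and 0.026). Against CRSsNP UT the ACTB difference was -0.80 (exact permutation test, adjusted p = 0.0952). For GAPDH the differences of nasal polyps from control UT, CRSwNP UT and CRSsNP UT were -0.64, -0.63 and -0.44, and none passed (exact permutation tests, adjusted p = 0.318, 0.386 and 0.386). Among the 3 UT groups the differences of both genes lay between -0.35 and 0.47, the lowest adjusted p of the exact permutation tests being 0.468.

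**Figure D1:**
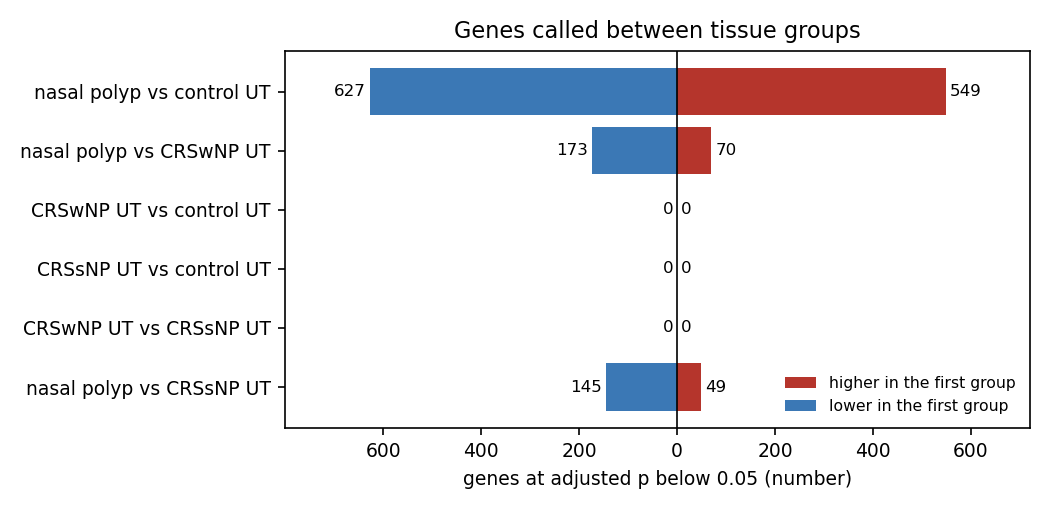
Number of genes at an adjusted p below 0.05 in limma for each of the 6 comparisons, with genes higher in the first group to the right and genes lower in it to the left. Nasal polyps differed from control UT in 549 higher and 627 lower genes, from CRSwNP UT in 70 and 173, and from CRSsNP UT in 49 and 145, while 0 genes were called between the UT groups.

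Nasal polyps differed from control UT in the largest number of genes. CCL18, a chemokine made by macrophages and dendritic cells, rose 57.4-fold (log2 4.31 ± 1.21 in polyps and -1.54 ± 0.73 in control UT, SD, n = 6 each; limma adjusted p = 0.00115). CLC, which encodes the Charcot-Leyden crystal protein of eosinophils, rose 52.8-fold (log2 5.72 ± 1.07 SE, limma adjusted p = 0.00396). The largest fall was that of PRB3, a salivary proline-rich protein, which was 74.3-fold lower (log2 -6.22 ± 0.89 SE, limma adjusted p = 0.00152). For each of CCL18, CLC and PRB3 all 6 polyp arrays lay beyond every control array.

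In limma 1176 of 18918 genes were called between nasal polyps and control UT, 549 higher and 627 lower, and 780 of them changed at least 2-fold. When 1 array was left out 592 to 1394 were called. The values of the groups did not overlap for 812 genes (4.29%), where chance gives 0.22%. With all arrays set to a common 75th percentile the split was 516 higher and 1039 lower. The other large rises were those of CLEC4GP1, a pseudogene of the lectin gene CLEC4G (29.9-fold), SHISA8 (27-fold), LGALS12 (23.2-fold), which encodes a galectin, and GFI1B (20.7-fold), a transcription factor of blood cells. The other large falls were those of CGREF1 (58-fold lower), the secretoglobins SCGB1D1 (57.8-fold lower) and SCGB2A2 (46.5-fold lower), GP2 (55.9-fold lower) and BPIFB6 (40-fold lower).

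The submucosal gland list fell in nasal polyps against control UT. Of its 25 genes 19 fell over all genes tested and 23 fell adjusted over the list alone, none rose, and their median log2 fold change was -2.37 (limma camera adjusted p = 3.38e-26; adjusted p = 0.0718 with an estimated correlation). Its members included LPO, the lactoperoxidase of gland secretions (log2 -4.24 ± 0.68 SE), and SLC12A2, a chloride cotransporter of secretory cells (-2.08 ± 0.33 SE). The score of the list differed by -2.59, lay below every control array on 6 of 6 polyp arrays, and passed the exact permutation test (adjusted p = 0.00914).

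Goblet and surface secretory genes also fell, at a median log2 fold change of -0.79: 6 of 20 fell over all genes tested, and 8 fell and 1 rose adjusted over the list alone (limma camera adjusted p = 8.37e-05; adjusted p = 0.126 with an estimated correlation). The secreted mucin gene MUC5AC differed by -0.01 ± 0.46 SE and did not pass, its other probe sets giving -0.45 to 0.89. The ciliated cell list did not pass (median log2 -0.27, limma camera adjusted p = 0.116), and its transcription factor FOXJ1 differed by -0.02 ± 0.78 SE.

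Several leukocyte lists rose in nasal polyps against control UT, but the plasma cell list did not pass (2 of 14 genes lower, median log2 0.24, limma camera adjusted p = 0.864). Of 14 macrophage and monocyte genes 8 rose over all genes tested and 13 adjusted over the list alone, with a median log2 fold change of 2.11 (limma camera adjusted p = 1.4e-11; adjusted p = 0.126 with an estimated correlation). AIF1, a marker of activated macrophages, rose by 2.33 ± 0.49 SE. The integrins ITGAM and ITGAX rose by 2.46 ± 0.46 and 2.34 ± 0.50 SE, but the other probe set of each gave -0.18 and -0.74. Of 15 mast cell and basophil genes 8 rose over all genes tested, and 13 rose and 1 fell adjusted over the list alone (median log2 2.08, limma camera adjusted p = 7.71e-10; adjusted p = 0.0718 with an estimated correlation). They included the mast cell protease genes CPA3 (2.64 ± 0.41 SE) and TPSB2 (2.89 ± 0.51 SE) and the prostaglandin D synthase gene HPGDS (2.32 ± 0.40 SE).

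Of 17 genes of alternatively activated macrophages 8 rose over all genes tested and 11 adjusted over the list alone (median log2 1.43, limma camera adjusted p = 3.92e-08; adjusted p = 0.126 with an estimated correlation); besides CCL18 they included F13A1 (3.26 ± 0.56 SE) and the scavenger receptor gene STAB1 (2.07 ± 0.41 SE). Of 17 dendritic cell genes 6 rose over all genes tested and 11 adjusted over the list alone (median log2 2.05, limma camera adjusted p = 1.04e-07; adjusted p = 0.0718 with an estimated correlation). Of 14 eosinophil genes 3 rose over all genes tested and 4 adjusted over the list alone (median log2 1.44, limma camera adjusted p = 0.00594; adjusted p = 0.126 with an estimated correlation). Of 29 type 2 inflammation genes 4 rose and 1 fell over all genes tested, and 8 rose and 1 fell adjusted over the list alone (median log2 1.25, limma camera adjusted p = 8.37e-05; adjusted p = 0.126 with an estimated correlation). The matrix gene POSTN differed by 2.52 ± 0.83 SE (limma adjusted p = 0.0737), the eotaxin gene CCL26 by 2.88 ± 1.43 SE (0.267) and the cystatin gene CST1 by 2.67 ± 1.79 SE (0.445), and none of them passed. Of the 3 other probe sets of POSTN 1 was called, and all went the same way. ALOX15 (0.83 ± 0.56 SE), KRT5 (0.50 ± 0.38 SE, and 0.84 without 1 polyp array that stood apart), LTF (-0.81 ± 0.28 SE) and STATH (-0.93 ± 0.31 SE) did not pass either.

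Of 19 endothelial genes 5 rose over all genes tested and 13 adjusted over the list alone (median log2 0.97, limma camera adjusted p = 3.92e-08; adjusted p = 0.15 with an estimated correlation), among them TIE1 (1.23 ± 0.29 SE), PECAM1 (0.93 ± 0.24 SE) and CLDN5 (2.15 ± 0.59 SE). Of 20 cell cycle genes 2 rose over all genes tested, the mitotic kinase genes AURKB (1.78 ± 0.48 SE) and BUB1 (2.12 ± 0.62 SE), and 15 adjusted over the list alone (median log2 1.42, limma camera adjusted p = 9.51e-08; adjusted p = 0.167 with an estimated correlation). Of the 4 other probe sets of BUB1, 3 went the same way. The B cell list rose (2 of 15 genes over all genes tested, 11 adjusted over the list alone, median log2 1.85, limma camera adjusted p = 2.11e-07). Its adjusted p = 0.126 with an estimated correlation. The T cell list rose too (3 of 17 genes, 8 adjusted over the list alone, median log2 1.18, limma camera adjusted p = 1.84e-06), with adjusted p = 0.231 with an estimated correlation.

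In all 25 of 38 lists passed camera for this comparison, 20 higher and 5 lower. With an estimated correlation 0 passed in limma camera (11 at an unadjusted p under 0.05), while 21 passed limma's fry and 20 the exact permutation test of their scores. Polyps also had a lower ACTB 3'/5' ratio. With the 3'/5' ratio as a covariate limma called 151 genes, 130 of them among the 1176, and with the gland marker score 399, of which 19 were among the 1176.

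**Figure D2:**
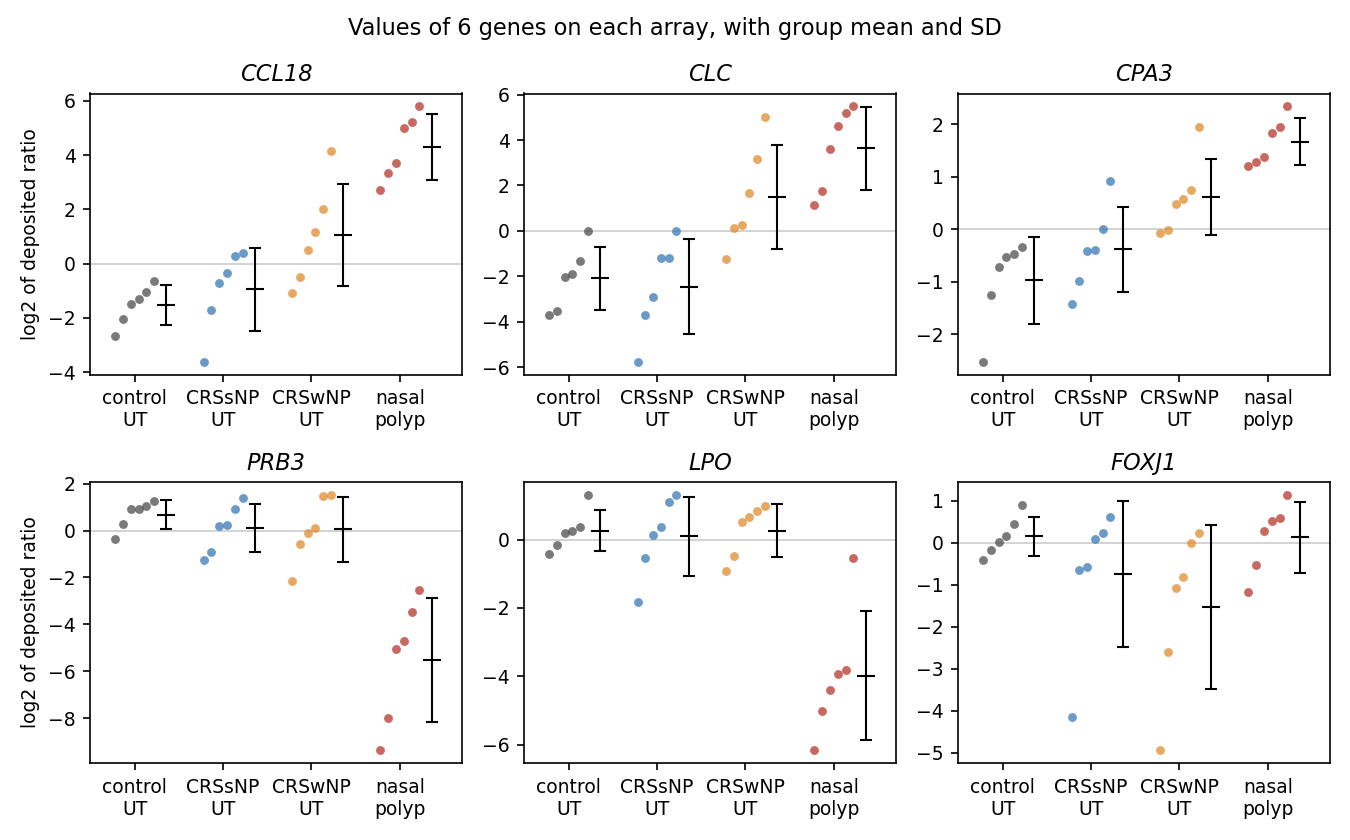
Log2 of the deposited ratio of 6 genes on each of the 24 arrays, points sorted within each group, with the group mean and SD beside them. CCL18 and CLC averaged 4.31 and 3.64 in polyps against -1.54 and -2.09 in control UT, PRB3 and LPO averaged -5.53 and -3.98 in polyps against 0.69 and 0.26 in control UT, and FOXJ1 averaged 0.14 and 0.16.

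Nasal polyps also had lower gland and secretory genes than the uncinate tissue of patients with the same diagnosis. CGREF1 fell 65.2-fold (log2 -6.03 ± 0.91 SE, limma adjusted p = 0.00537), PRB3 47.8-fold and BPIFB6 47.9-fold, each below every CRSwNP UT array on 6 of 6 polyp arrays. GP2 (52.8-fold lower), LACRT (33.8-fold lower) and REG4 (31.1-fold lower) completed the 6 largest falls, the other 2 probe sets of REG4 giving -1.81 and -0.42. CCL18 was 9.58-fold higher (log2 3.26 ± 0.78 SE, limma adjusted p = 0.0426), above the CRSwNP UT mean on 6 of 6 polyp arrays, a call that 16 alternatives lost. CLC differed by 2.14 ± 1.07 SE and did not pass (limma adjusted p = 0.262).

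The submucosal gland list fell against CRSwNP UT at a median log2 fold change of -2.68: 17 of 25 genes fell over all genes tested and 25 adjusted over the list alone (limma camera adjusted p = 1.57e-44; adjusted p = 0.0163 with an estimated correlation). The list score lay below every CRSwNP UT array on 5 of 6 polyp arrays. LPO was 18.9-fold lower and CRISP3 13.5-fold lower. Of 20 goblet and surface secretory genes 5 fell over all genes tested and 10 adjusted over the list alone (median log2 -0.81, limma camera adjusted p = 1.25e-07; adjusted p = 0.0455 with an estimated correlation), among them TSPAN8 (-1.96 ± 0.36 SE), MSMB (-2.21 ± 0.42 SE) and the trefoil factor gene TFF1 (-3.48 ± 0.71 SE). Of 18 ion and water transport genes 3 fell over all genes tested and 4 adjusted over the list alone, while 8 were above 0 and the median log2 was -0.10 against 0.22 for all genes (limma camera adjusted p = 0.000474; adjusted p = 0.0455 with an estimated correlation). The 3 were the carbonic anhydrase gene CA2 (-2.71 ± 0.42 SE), SLC12A2 (-1.98 ± 0.33 SE) and the water channel gene AQP5 (-1.37 ± 0.33 SE). These 3 lists were the ones that passed with an estimated correlation.

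Cell cycle (median log2 1.27), endothelial (0.77), macrophage and monocyte (1.31) and B cell genes (1.52) rose against CRSwNP UT as lists, at limma camera adjusted p of 9.93e-05, 0.000277, 0.000474 and 0.000626. With an estimated correlation adjusted p = 0.48, 0.48, 0.547 and 0.48, and 0 of their members passed over all genes tested, while 9, 1, 8 and 7 rose adjusted over the list alone. Mast cell and dendritic cell genes rose as lists too (median log2 1.07 and 1.25, both limma camera adjusted p = 0.00343; adjusted p = 0.48 for both with an estimated correlation). Plasma cell genes fell as a list (median log2 -0.20, limma camera adjusted p = 0.00182; adjusted p = 0.48 with an estimated correlation). Their score differed by -0.21 and did not pass (exact permutation test, adjusted p = 0.238). The type 2 inflammation and eosinophil lists did not pass (median log2 0.92 and 1.09, limma camera adjusted p = 0.156 and 0.255), though both passed limma's fry (adjusted p = 0.0361 and 0.0265). The ciliated cell list was higher (median log2 0.79, limma camera adjusted p = 0.025; adjusted p = 0.654 with an estimated correlation), and was called lower with the gland marker score as a covariate. Among single genes the largest rises were those of NFKB2 (12.5-fold), CBL (10.1-fold), ANKLE1 (9.84-fold), CDKN2D (9.49-fold) and MECOM (8.65-fold), which encode a transcription factor, a ubiquitin ligase, a nuclease, a cell cycle inhibitor and a transcription factor. The other probe sets of NFKB2 ranged from -0.31 to 0.86 and those of MECOM from -0.22 to 0.55. The 4 others of CBL ranged from 0.76 to 1.26, and none of these was called. For NFKB2 and MECOM polyps differed from control UT by 1.458 and 0.576, and CRSwNP UT by -2.185 and -2.535 without passing. For CBL polyps differed from control UT by 3.008 and CRSwNP UT by -0.322. In the fixed panel CCL26 (1.61), POSTN (1.90), ALOX15 (0.74), CST1 (0.98), LTF (-1.05), STATH (-1.12), FOXJ1 (1.67), KRT5 (0.73) and MUC5AC (0.00) did not pass, and the other probe sets of POSTN gave -0.04 to 1.41. Without 1 CRSwNP UT array that stood apart POSTN differed by 1.10.

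In all 243 genes were called between nasal polyps and CRSwNP UT, 70 higher and 173 lower, the median over all genes being shifted by 0.22. Quantile normalization brought the shift to 0.02 and the split to 20 higher and 189 lower. A common 75th percentile gave 36 higher and 344 lower, and a common median 58 and 307. The values did not overlap for 218 genes (1.15%, 0.22% by chance). Of the lists 19 passed camera, 3 passed with an estimated correlation, 15 passed fry, and 0 passed the exact permutation test of scores, in which 17 had an unadjusted p under 0.05. The ACTB 3'/5' ratio was lower in polyps here too, and with the 3'/5' ratio as a covariate limma called 0 genes (1606 at an unadjusted p under 0.05), though the median log2 fold change of the 173 lower genes only went from -1.57 to -1.43. It called 2 with the gland marker score, 5 in a fit of these 12 arrays alone, and 71 to 863 when 1 array was left out. With the gland marker score the median of the 173 lower genes went to -0.27 (median SE 0.412), but some of these genes are part of that score. With the replicate number as a block limma called 393, 183 higher and 210 lower. Same-number arrays of every group shared a block, so this was not a paired test of polyps and CRSwNP UT.

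Between CRSwNP UT and control UT no single gene passed in limma. CLC was 12-fold higher in CRSwNP UT (log2 3.59 ± 1.07 SE, n = 6 each) and CCL18 5.99-fold higher (2.58 ± 0.78 SE), above the control mean on 6 of 6 arrays each. Neither passed (limma adjusted p = 0.368 for both). FOXJ1 was 3.24-fold lower (limma adjusted p = 0.499). Limma called 0 of 18918 genes, while 1827 had an unadjusted p under 0.05, and the lowest adjusted p was 0.245, for TH (2.88 ± 0.52 SE), the gene of tyrosine hydroxylase, and SHISA8 (3.64 ± 0.69 SE). With the replicate number as a block both were called (limma adjusted p = 0.0426 and 0.0316), as they were without 1 control array. Control subjects and patients are different people, so an equal number marks no pair between these groups. Same-number arrays of the 2 groups correlated above 0.1 in 0 of 6 pairs (median 0.023, against -0.007 for other numbers). Other genes with small p in their direction were SIRPB1 (1.31), HHLA2 (-3.69), GDPD1 (-0.81) and PPP1R14D (-1.22), and both other probe sets of GDPD1 and 1 of the 2 of HHLA2 went the other way.

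As lists, the alternatively activated macrophage (median log2 0.59, limma camera adjusted p = 1.59e-08), macrophage and monocyte (0.74, 2.44e-08) and mast cell genes (0.66, 2.67e-08) were higher in CRSwNP UT than in control UT, relative to a median of all genes of -0.14. With an estimated correlation adjusted p = 0.192, 0.243 and 0.192. None of their members passed over all genes tested; 2, 0 and 4 rose adjusted over the list alone. The ciliated cell list was lower, at a median of -1.09 with 0 of 25 genes called either way (limma camera adjusted p = 5.67e-07; adjusted p = 0.519 with an estimated correlation). Plasma cell (0.34, limma camera adjusted p = 6.59e-06; adjusted p = 0.233 with an estimated correlation) and type 2 inflammation genes (0.28, limma camera adjusted p = 8.79e-05; adjusted p = 0.233 with an estimated correlation) were higher.

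In all 20 lists passed limma's camera between CRSwNP UT and control UT, 19 higher and 1 lower. With an estimated correlation 0 passed (7 at an unadjusted p under 0.05), 0 passed limma's fry (4) and 0 the exact permutation test of scores (4). In that last test the mast cell score was 0.82 higher, above every control array on 6 of 6 CRSwNP UT arrays, with an exact p of 0.00216, the smallest it can give, and an adjusted p of 0.0823. In each of the 2 groups 1 array stood apart, and without both the mast cell score was only 0.40 higher. The values of the groups did not overlap for 152 genes (0.8%, 0.22% by chance). In the fixed panel CCL26 (1.27), POSTN (0.61), ALOX15 (0.10), CST1 (1.69), LTF (0.24), STATH (0.18), KRT5 (-0.23) and MUC5AC (-0.01) did not pass, and POSTN differed by 1.41 without the CRSwNP UT array that stood apart for it.

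CRSsNP UT differed from control UT in 0 genes in limma, with 973 at an unadjusted p under 0.05. The lowest adjusted p was 0.117, for DENND2A (2.88 ± 0.49 SE), and p was also small for ZNF556 (-3.05 ± 0.57 SE), TH (2.65 ± 0.52 SE), OR1Q1 (2.97), INTS6 (-0.69) and ZBTB16 (-2.22); the other probe sets of DENND2A and OR1Q1 gave values from -0.73 to 0.18 and -1.49. CLC differed by -0.38 ± 1.07 SE and CCL18 by 0.59 ± 0.78 SE (limma adjusted p = 0.988 and 0.972), the other probe set of CCL18 giving -0.56. Other genes with large rises in polyps were higher here without passing: GFI1B by 2.61 ± 0.75 SE and SHISA8 by 2.60 ± 0.69 SE (limma adjusted p = 0.919 for both), above the control mean on 6 of 6 arrays each, and CLEC4GP1 by 2.00 ± 0.73 SE (0.947). The ciliated cell list was lower, at a median of -0.89 with 0 of 25 genes called (limma camera adjusted p = 9.2e-08; adjusted p = 0.882 with an estimated correlation). B cell (median log2 0.71), macrophage and monocyte (0.72) and endothelial genes (0.41) were higher as lists, at limma camera adjusted p of 4.56e-05, 4.81e-05 and 0.000118; with an estimated correlation adjusted p = 0.882 for each.

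Of the lists 9 passed limma's camera between CRSsNP UT and control UT, 8 higher and 1 lower. None (0) of them passed with an estimated correlation, 0 passed limma's fry and 0 the exact permutation test of scores, with 0 lists at an unadjusted p under 0.05 in each of these. The values of the groups did not overlap for 58 genes (0.31%, 0.22% by chance). In the fixed panel CCL26 (-0.90), POSTN (-0.37), ALOX15 (-1.24), CST1 (-2.01), LTF (-0.04), STATH (-0.11), FOXJ1 (-0.90), KRT5 (-0.12) and MUC5AC (0.18) did not pass, and without 1 CRSsNP UT array that stood apart FOXJ1 differed by -0.21.

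The uncinate tissue of the 2 forms of CRS was compared directly. CLC was 15.7-fold higher in CRSwNP UT than in CRSsNP UT (log2 3.97 ± 1.07 SE, n = 6 each), CST1 13-fold and CCL26 4.48-fold, and none passed (limma adjusted p = 0.958 for each). Limma called 0 genes, with 910 at an unadjusted p under 0.05, and the lowest adjusted p was 0.657. Genes with small p are named here apart from those with LOC, orf, LINC or antisense symbols. Higher were HPYR1 (3.03) and DAOA (2.50) besides CLC, and lower were INCENP (-2.24), MYH6 (-2.85) and GDPD1 (-0.72). The other probe sets of DAOA and GDPD1 went the other way.

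The type 2 inflammation list was higher in CRSwNP UT than in CRSsNP UT, at a median of 0.22 and a mean of 0.62 (limma camera adjusted p = 2.83e-05; adjusted p = 0.236 with an estimated correlation), and so was the eosinophil list (median log2 0.42, limma camera adjusted p = 0.000319; adjusted p = 0.188 with an estimated correlation). None of the genes of either list passed over all genes tested; adjusted over the list alone 0 and 2 rose, the latter being CLC and HRH4. In all 13 lists passed limma's camera, each of them higher, while the median of all genes was shifted by -0.12. None (0) passed with an estimated correlation (4 at an unadjusted p under 0.05), and 0 passed limma's fry or the exact permutation test of scores (0 at an unadjusted p under 0.05 in both). The values did not overlap for 23 genes (0.12%, 0.22% by chance). In the fixed panel CCL18 (2.00), POSTN (0.98), ALOX15 (1.34), LTF (0.28), STATH (0.29), FOXJ1 (-0.80), KRT5 (-0.11) and MUC5AC (-0.19) did not pass. Without 1 array that stood apart, POSTN differed by 1.78 (a CRSwNP UT array) and FOXJ1 by -1.48 (a CRSsNP UT array).

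Nasal polyps were last compared with CRSsNP UT. CLC rose 68.8-fold (log2 6.10 ± 1.07 SE, limma adjusted p = 0.0119) and CCL18 38.3-fold (5.26 ± 0.78 SE, limma adjusted p = 0.00589), each above every CRSsNP UT array on 6 of 6 polyp arrays. Among the falls were CGREF1 (51.5-fold lower), PRB3 (49.7-fold lower), BPIFB6 (30.7-fold lower), REG4 (26.1-fold lower), HTN1, a salivary histatin gene (26.1-fold lower), and RALYL (24.3-fold lower). The other 2 probe sets of REG4 gave -0.73 and 0.06. VSTM1 (13.1-fold), TKT (11.3-fold), CLEC4G (10.8-fold) and DOT1L (9-fold) were higher. For TKT and DOT1L polyps differed from control UT by only 0.785 and 0.811. CRSsNP UT differed from control UT by -2.708 and -2.36 for these 2, without passing. For VSTM1 and CLEC4G 6 of 6 polyp arrays lay beyond every control array, and for TKT and DOT1L 2 each. The other 2 probe sets of TKT gave only 0.33 and 0.57, and those of DOT1L -0.07 and 0.11, and none of these was called.

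Of 25 submucosal gland genes 14 fell over all genes tested and 24 adjusted over the list alone (median log2 -2.14, limma camera adjusted p = 1.05e-34; adjusted p = 0.052 with an estimated correlation), LPO being 16.8-fold and SLC12A2 4.24-fold lower, and the list score lay below every CRSsNP UT array on 5 of 6 polyp arrays. Of 15 mast cell and basophil genes 3 rose over all genes tested and 10 adjusted over the list alone (median log2 1.64, limma camera adjusted p = 1.85e-08; adjusted p = 0.0777 with an estimated correlation): HDC, the histidine decarboxylase that makes histamine (1.85 ± 0.35 SE), CPA3 (2.05 ± 0.41 SE) and RGS13 (1.87 ± 0.42 SE). ITGAM was the macrophage and monocyte gene that rose over all genes tested (2.15 ± 0.46 SE, its other probe set giving -0.56), and 9 of 14 rose adjusted over the list alone (median log2 1.31, limma camera adjusted p = 3.63e-07; adjusted p = 0.25 with an estimated correlation). The dendritic cell genes CD1A (2.94 ± 0.57 SE) and CD1C (2.32 ± 0.52 SE), which encode lipid antigen-presenting molecules, rose in a list that rose at limma camera adjusted p = 1.75e-06 (median log2 1.14; adjusted p = 0.0935 with an estimated correlation). The eosinophil list rose (2 of 14 genes over all genes tested, 4 adjusted over the list alone, median log2 1.41, limma camera adjusted p = 0.000225; adjusted p = 0.0777 with an estimated correlation). The type 2 inflammation list rose as well (1 of 29 genes, with 11 higher and 1 lower adjusted over the list alone, median log2 1.23, limma camera adjusted p = 6.31e-06; adjusted p = 0.103 with an estimated correlation).

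In all 194 genes were called between nasal polyps and CRSsNP UT, 49 higher and 145 lower, and the values did not overlap for 147 (0.78%, 0.22% by chance). Of the lists 27 passed limma's camera, 0 with an estimated correlation (8 at an unadjusted p under 0.05), and 15 passed fry. The 7 that passed the exact permutation test of scores were type 2 inflammation, eosinophil, mast cell, alternatively activated macrophage, dendritic cell, eicosanoid and, lower, submucosal gland. The ACTB 3'/5' ratio differed by -0.80 here. With the 3'/5' ratio as a covariate limma called 4 genes, with the gland marker score 5, in a fit of these 12 arrays alone 1, and when 1 array was left out 21 to 673. In the fixed panel CCL26 (3.77), POSTN (2.89), ALOX15 (2.07), CST1 (4.67), LTF (-0.77), STATH (-0.83), FOXJ1 (0.87, and 0.19 without 1 CRSsNP UT array that stood apart), KRT5 (0.62) and MUC5AC (-0.19) did not pass. The 3 other probe sets of POSTN went the same way (0.81 to 2.71), and 1 of them was called.

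**Figure D3:**
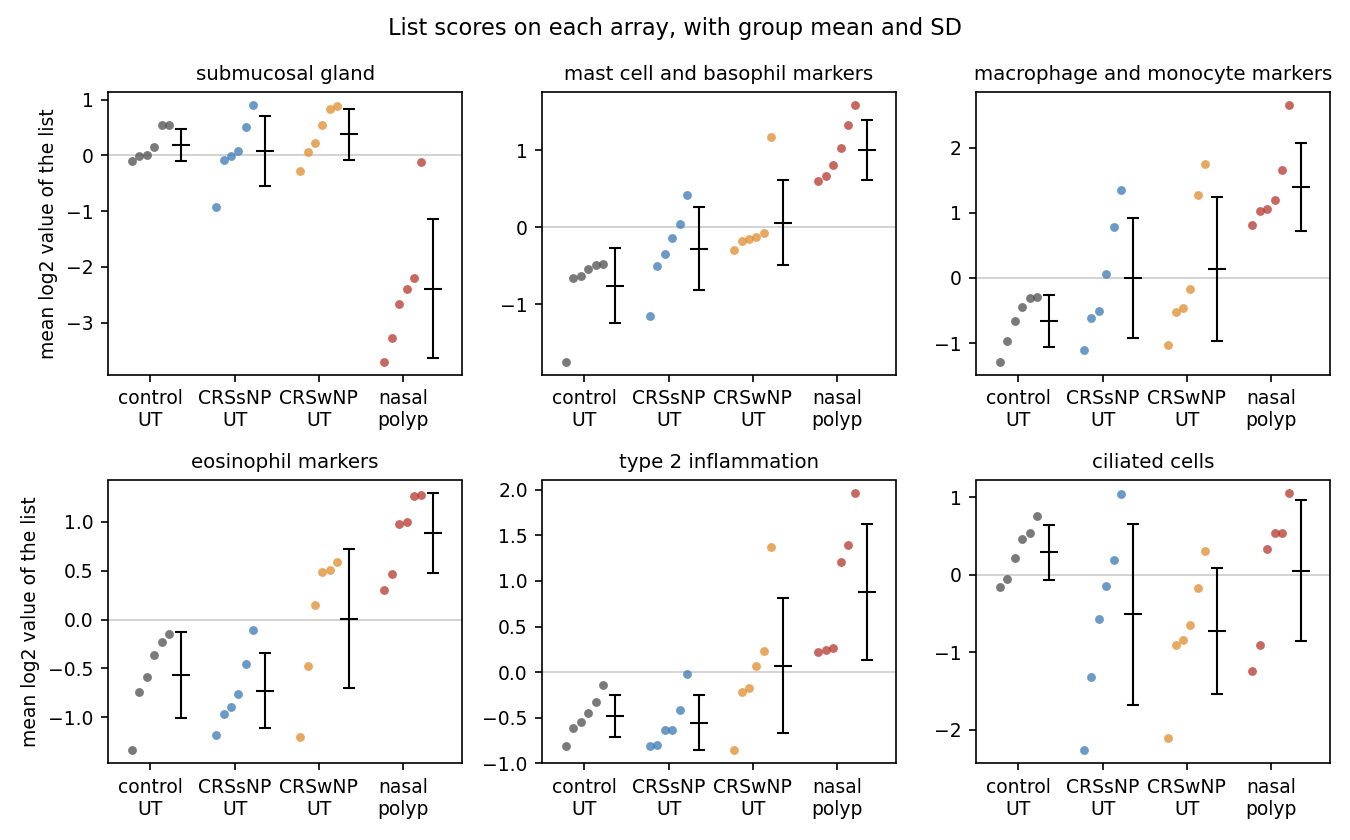
Score of 6 gene lists, the mean log2 value of their genes, on each of the 24 arrays, points sorted within each group, with the group mean and SD beside them. The gland list score averaged -2.39 in polyps and 0.19, 0.08 and 0.38 in control UT, CRSsNP UT and CRSwNP UT, the mast cell score 1.01, -0.76, -0.28 and 0.06, and the ciliated cell score 0.05, 0.29, -0.51 and -0.73 in the same order.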

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

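The tests of the 3'/5' ratio as a covariate, of mast cell against ciliated cell scores and of the genes that do not follow the gland score were chosen only after the result was seen.

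Genes lower in nasal polyps than in CRSwNP UT. Within the 3 UT groups (18 arrays) the 156 of these genes outside the gland list followed the gland marker score (mean z-score of the gland genes), at a median correlation of 0.672 (Spearman 0.588, permutation p = 3e-04), 0.48 without the 2 arrays farthest from the median, and -0.196 for other genes. Less gland tissue in the polyp samples is therefore a candidate explanation, whether by sampling or as a trait of polyps, which was not tested. With the gland marker score as a covariate the median log2 fold change of all 173 lower genes went from -1.57 to -0.27 (median SE 0.412). Some of these 173 genes are part of that score. Lower RNA integrity in polyps is argued against, since these genes had a median correlation of 0.221 with the 3'/5' ratio, not a negative one, and the ratio was lower in polyps, not higher. For other genes the median correlation was -0.288. With the lower ratio of polyps both signs go in the direction seen, as the median of all genes was 0.22 higher in polyps. Some other difference in RNA integrity cannot be told apart: with the 3'/5' ratio as a covariate the median log2 fold change went from -1.57 (median SE 0.34) to -1.43 (0.387) and 0 genes stayed called in limma (1606 at an unadjusted p under 0.05), so the fold was smaller and its error larger.

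Leukocyte and endothelial lists higher in nasal polyps than in control UT. If less gland RNA raised every other cell type alike, mast cell and ciliated cell scores would rise together. The mast cell score differed by 1.765 and the ciliated cell score by -0.237, so they moved apart by 2.00 (exact permutation p = 0.00216, the smallest it can give). This pair was picked after both scores were seen, so that p is not an independent test. The values show only that these 2 lists did not rise alike. Array scaling is argued against for the macrophage and monocyte list only, which kept a median of 1.97 after quantile normalization. A difference in RNA integrity cannot be told apart, since with the 3'/5' ratio as a covariate that median went from 2.11 (median SE 0.501) to 1.34 (0.519). A higher share of leukocytes in polyps stays open, as a hypothesis.

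Of the 6 arrays of a group 2 in CRSsNP UT, 3 in CRSwNP UT and 0 in control UT correlated more with polyps than with their own group, and 1 CRSsNP UT array did so most (by 0.215; highest in CRSwNP UT 0.106). A swap with a polyp array is argued against, as 0 of 6 polyp arrays correlated more with the CRSsNP UT arrays than with other polyps. Its gland marker score, a mean z-score and not the list score, was -0.48, against 0.25 to 0.90 on the other CRSsNP UT arrays, and over 7051 genes that do not follow the gland score the excess was 0.107. A gland-poor piece of tissue cannot be told apart from other explanations: that value lies between gone and kept, and the excess was 0.491 once the slope of each gene on the gland score was removed, where errors of the slopes are shared by arrays with a low score. Without this array 673 genes were called between polyps and CRSsNP UT, 318 higher and 355 lower.

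Other splits of the 12 arrays of a comparison (100 drawn of 462) were fitted in the same way. For genes, no other split drawn gave as many as the 1176 between polyps and control UT (highest other 139). The same held for the 243 against CRSwNP UT (highest other 3) and the 194 against CRSsNP UT (highest other 130). The real split alone, 1 of 100, is the smallest share these splits can give, and most of the 462 were not drawn, so chance is made less likely but not excluded. For the 3 comparisons among UT groups limma called 0 genes, a count that every split reaches, so the splits cannot test it (highest others 1, 2 and 21). For lists, 3, 4 and 2 of 100 splits gave as many as the 25, 19 and 27 of the polyp comparisons with control UT, CRSwNP UT and CRSsNP UT (highest others 28, 24 and 27). Each share was under 0.05, but some other splits gave as many lists or more, so this count alone does not exclude chance. For the 20 lists of CRSwNP UT against control UT 3 splits gave as many (highest other 22), a share also under 0.05, but 0 of these lists passed with an estimated correlation in limma camera (7 at an unadjusted p under 0.05), 0 in fry (4) and 0 in exact permutation tests of scores (4). The share was larger, and chance is not excluded either, for the 9 lists of CRSsNP UT against control UT (44 splits, highest other 19). The same holds for the 13 lists of CRSwNP UT against CRSsNP UT (32 splits, highest other 23).

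In 13 of 208 groups of 6 arrays 1 array stood far from the others, where chance gives about 10.4. The gap to the nearest array, as a share of the range of the group, was 0.63 for POSTN in CRSwNP UT (lowest array -4.22, next -0.37), 0.732 for FOXJ1 in CRSsNP UT (-4.14 and -0.65) and 0.645 for KRT5 in polyps. For list scores it was 0.853 for mast cells in control UT (lowest array) and 0.853 in CRSwNP UT (highest array). In CRSwNP UT it was 0.735 for interferon response, 0.803 for endothelial cells, 0.86 for smooth muscle, 0.643 for coagulation (each the highest array) and 0.811 for junctions (the lowest). It was 0.65 for squamous epithelium in CRSsNP UT, 0.65 for smooth muscle in control UT and 0.756 for extracellular matrix in polyps.

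The changes of 13 lists against control UT differed between CRSwNP UT and CRSsNP UT in limma camera with the preset correlation. The control values cancel in this difference, so it is the direct comparison of the 2 groups. These are the 13 lists already given for it and add no further evidence. The differences, as medians, were 0.222 for type 2 inflammation, 0.415 for eosinophils, 0.356 for mast cells, 0.477 for neutrophils, 0.21 for alternatively activated macrophages, 0.083 for T cells and 0.243 for plasma cells. They were 0.066 for dendritic cells, 0.309 for glands, 0.285 for goblet cells, 0.089 for eicosanoids, 0.047 for hypoxia and 0.2 for the oncostatin M family. With an estimated correlation 0 of these passed in limma camera (4 at an unadjusted p under 0.05). Without the CRSwNP UT array that stood apart for mast cells, the difference in the mast cell score went from 0.336 to 0.113.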

How the results depend on the processing

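The trend in the spread, the settings planned for intensities, the common median, leaving out the array with the lowest median, list scores per array and the 3'/5' covariate were chosen after seeing the data; the other alternatives were not. For the 24 counts and ratios 135 of 180 alternative values stayed within 1.5 times the reported count or on the same side of the threshold, 35 were weaker and 10 stronger. Only the 3'/5' ratios could be labelled reversed, and 0 were. A count has no direction, so it does not show a list that changed sides. The ciliated cell list did so between polyps and CRSwNP UT with the gland marker score as a covariate. Of 1782 values of 11 panel genes 1731 stayed called or stayed uncalled, 25 lost a call, 26 gained one and 0 reversed a called value. Most of the 1731 were uncalled throughout. The only panel calls reported were those of CCL18 in each polyp comparison and of CLC in polyps against control UT and CRSsNP UT. The 25 losses were all of these calls, and CCL18 between polyps and CRSwNP UT lost its call in 16 alternatives. The stricter filter and the 12-array fits test fewer genes or use fewer arrays; for every other change below the cause was not tested.

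Genes called between polyps and control UT (1176) numbered 707 with the stricter filter, 780 at 2-fold or more, 1922 with array weights, 399 with the gland marker score and 151 with the 3'/5' ratio as a covariate. Between polyps and CRSwNP UT (243) they numbered 106 with the stricter filter, 380 at a common 75th percentile, 365 at a common median, 97 with the settings planned for intensities and 103 without the array with the lowest median. They numbered 5 in the fit of these groups alone (ANKLE1, BEND7, CDKN2D, LINC01798, SLC12A2), 2 with the gland score (FARS2-AS1, IP6K3) and 0 with the 3'/5' ratio (limma, 1606 at an unadjusted p under 0.05). Between polyps and CRSsNP UT (194) they numbered 108 with the stricter filter, 611 with array weights, 1 in the fit of these groups alone (BEND7), 5 with the gland score (CXorf58, DHDDS-AS1, GSTA3, IP6K3, LCA5L) and 4 with the 3'/5' ratio (BEND7, CCL18, LINC01798, SIRPB1). Between CRSsNP UT and control UT 1 gene was called after quantile normalization and 1 with array weights (DENND2A in both), and 2 in the fit of these groups alone (FSTL5, TSGA13). These few genes are named after their values were seen.

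The labels do not say whether equal replicate numbers mark 1 patient, so the numbers were not taken as pairs. Same-number arrays of CRSwNP UT and polyps correlated above 0.1 in 3 of 6 pairs (median 0.074, against -0.004 for other numbers), and 3 of 6 CRSwNP UT and 5 of 6 polyp arrays correlated best with their own number. With the number as a block 393 genes were called between polyps and CRSwNP UT (183 higher, 210 lower). It called 2 between CRSwNP UT and control UT (SHISA8, TH), where an equal number cannot mark 1 patient. The block moved no other count by over 1.5 times.

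Lists called with an estimated correlation were 0, 3, 0, 0, 0 and 0 for polyps against control UT, polyps against CRSwNP UT, CRSwNP UT against control UT, CRSsNP UT against control UT, CRSwNP UT against CRSsNP UT and polyps against CRSsNP UT (limma camera, 11, 4, 7, 0, 4 and 8 at an unadjusted p under 0.05). For the 3 comparisons among UT groups, in the same order, fry in limma called 0, 0 and 0 (4, 0 and 0 unadjusted) and list scores per array 0, 0 and 0 in exact permutation tests (4, 0 and 0). Polyps against CRSwNP UT gave 0 lists by score (17 unadjusted, exact permutation test) and 8 with the gland score. Polyps against CRSsNP UT gave 7 by score, 15 by fry and 14 with the gland score. With the stricter filter CRSwNP UT against control UT gave 11 lists, CRSsNP UT against control UT 4 and CRSwNP UT against CRSsNP UT 6; without a filter the last gave 8. The GAPDH difference between polyps and control UT was -0.26 with the 3'/M ratio and passed (exact permutation test, adjusted p = 0.0389); the other 3'/M differences kept their calls.

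With 1 array left out the gene counts ran from 592 to 1394 for polyps against control UT, 71 to 863 against CRSwNP UT and 21 to 673 against CRSsNP UT. They ran from 0 to 2 for CRSwNP UT against control UT, 0 to 2 for CRSsNP UT against control UT and 0 to 1 for CRSwNP UT against CRSsNP UT. Counts moved over 1.5 times for polyps against control UT without 1 control array (745) or any of 3 polyp arrays (592, 682 and 781). Against CRSwNP UT they did so without any of 4 CRSwNP UT arrays (71, 92, 103 and 863) or 5 polyp arrays (75, 88, 94, 109 and 553), and against CRSsNP UT without any of 5 CRSsNP UT arrays (21, 30, 52, 96 and 673) or 5 polyp arrays (51, 54, 56, 104 and 376). Leaving out 1 control array called SHISA8 and TH against CRSwNP UT and DENND2A and TH against CRSsNP UT, leaving out another called ZNF556 in both, and leaving out 1 CRSwNP UT array called ADAMTS9-AS2 against CRSsNP UT. List counts, in the order above, ran from 22 to 29, 14 to 20, 14 to 24, 7 to 13, 7 to 20 and 25 to 29; the 7 and 20 of CRSwNP UT against CRSsNP UT came without 1 CRSsNP UT and 1 CRSwNP UT array. The number of arrays limits the precision, and since ratios hide brightness, which genes lie near background is unknown.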

Other observations

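The members named here were chosen after their values were seen. Among 34 chemokine genes 6 rose and 2 fell in nasal polyps against control UT over all genes tested, and 8 rose and 2 fell adjusted over the list alone (median log2 0.66, limma camera adjusted p = 0.00131; adjusted p = 0.231 with an estimated correlation). The monocyte attractant genes CCL8 (3.71 ± 0.70 SE), CCL2 (2.25 ± 0.56 SE) and CCL23 (4.21 ± 1.17 SE) rose. So did CCL22 (3.20 ± 0.81 SE), which attracts Th2 cells, and the eotaxin gene CCL11 (2.80 ± 0.72 SE). The mucosal chemokine genes CCL28 (-1.78 ± 0.35 SE) and CXCL17 (-0.75 ± 0.22 SE) fell. The cytokine gene IL4 rose (1.70 ± 0.47 SE), as did the eosinophil genes SIGLEC8 (3.16 ± 0.77 SE) and ADGRE1 (2.62 ± 0.44 SE).

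Of 24 eicosanoid genes 4 rose and 1 fell in polyps against control UT over all genes tested, and 8 rose and 1 fell adjusted over the list alone (median log2 0.85, limma camera adjusted p = 3.91e-05; adjusted p = 0.132 with an estimated correlation). Those that rose were the leukotriene pathway genes ALOX5 (1.18 ± 0.28 SE), ALOX5AP (1.58 ± 0.37 SE) and CYSLTR1 (1.67 ± 0.32 SE), and HPGDS; the phospholipase gene PLA2G2A fell (-3.13 ± 0.91 SE). The coagulation list did not pass (median log2 0.43, limma camera adjusted p = 0.07), though 4 of its 16 genes rose and 1 fell: F13A1 (3.26), the urokinase gene PLAU (1.72 ± 0.49 SE), PROCR (0.85 ± 0.22 SE) and SERPINE2 (0.74 ± 0.20 SE) were higher and F5 was lower (-2.26 ± 0.44 SE). In the complement list, which did not pass (limma camera adjusted p = 0.0963), CFI rose (1.70 ± 0.31 SE) and the regulator gene CD46 fell (-0.57 ± 0.16 SE). List scores differed by 0.40 for coagulation and 0.52 for complement, and both passed exact permutation tests (adjusted p = 0.0194 for each).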
